A study of Mus musculus with 2 samples.

How the data were processed

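Gene expression was measured with Visium, which captures polyadenylated RNA from a tissue section on a hexagonal grid of barcoded spots and counts molecules by their identifiers (UMIs). There were 2 samples, 1 section of 10 µm from the ischemic hemisphere of a mouse labelled Ppm1d-/- and 1 from a wild-type mouse, each taken 24 h after a 30 min occlusion of the middle cerebral artery. The genotype label of the first sample reads Ppm1d-/- in 1 place and knockdown in another. Both samples carry the same batch label. The deposited values are raw UMI counts per gene and spot, made with Space Ranger on the mm10 genome build per the submitters' processing notes; the version of Space Ranger is not given in the sources used here. The deposited counts cover 31053 genes, 35 of whose symbols are repeated, and only spots under tissue.

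Spots with at least 500 UMIs were kept, which left out 1 spot of each section and kept 2841 spots of the section labelled Ppm1d-/- and 2845 of the wild-type section. The counts of a gene were summed over the spots of a section or region and divided by the sum of all genes, and scaled to CPM, counts per 1000000. With 1 animal per genotype there is no test across animals, no p-value and no standard error, and spots are not replicates. Intervals are exact at 95%: Poisson for a sum, Clopper-Pearson for a share, and Clopper-Pearson on the split of the pooled count for a ratio of sums. They cover counting error only. A gene counted as higher or lower by size with a ratio of at least 1.5-fold, an interval excluding 1 and at least 100 UMIs over both sections. A gene with no UMIs in 1 section has no finite ratio. It was left out of list medians and of the ranking of named genes, but could count as higher or lower by size.

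Regions were found by Leiden clustering at resolution 1 (15 neighbours, 30 principal components) of log-transformed counts scaled to 10000 per spot. The 2000 variable genes were chosen within each section and each gene was scaled within its section, with values clipped at 10. Genes of the lists about injury, immunity, vessels and stress, the genes that define injury regions, Ppm1d, sex-linked, mitochondrial and haemoglobin genes were left out of the clustering, 370 in all. A region was an injury region when the median fold, over 10 genes (Atf3, Hmox1, Timp1, Cd44, Hspb1, Emp1, S100a11, Tnfrsf12a, Fosl1 and Sprr1a), of its CPM over all other spots of the section was at least 2 in each section where it held at least 20 spots. A region was matched with at least 50 spots in each section. Region-matched ratios standardise CPM over the matched regions by their share of the pooled spots. Regions are called by number and leading genes, not as cell types. The comparisons were between the sections over all spots, over injury regions and over other regions, and between injury and other regions within each section. Distance was counted in array steps from the nearest injury spot, with rings of 1 to 3 and 4 to 6 steps.

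The 39 gene lists were fixed before the data were examined, as were the rules above, the rule for named genes and most of the alternatives named at the end. The 8 primary lists were p53 target genes, cytokines, chemokines and NF-kB feedback, neutrophil markers, monocyte and macrophage markers, homeostatic microglia markers, phagocytic microglia markers, reactive astrocyte genes, and endothelial and blood-brain barrier genes. The others covered type I interferon response, complement and MHC class I, lymphocytes, astrocyte identity, activated endothelium, mural cells, meningeal and fibroblast matrix, matrix proteases and the plasmin system, myelin, oligodendrocyte precursors, neurons and their synapses, immediate early genes, heat shock, the unfolded protein response, hypoxia and glycolysis, the respiratory chain, ribosomal proteins, cell death, NRF2 and metallothioneins, the cell cycle, DNA damage signalling, red blood cells, choroid plexus and brain areas. A list is given by the median log2 ratio of its members with at least 20 UMIs, and by the percentile of that median among 10000 random lists of like size and expression (20 bins). A list stood apart at or below percentile 2.5 or at or above 97.5, as a description of these sections. Genes of the random lists were drawn independently, so a list whose members vary together can stand apart more readily. Between the sections, members counted as higher or lower by at least 0.32 on the log2 scale with an interval excluding 0.

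Named genes of the whole-section comparison were the 12 highest and 12 lowest with at least 200 UMIs, the same direction after standardising over regions by at least 0.32, and the same direction in at least 75% of matched regions with at least 20 UMIs (at least 3 such regions). In injury regions they were the 8 highest and 8 lowest with at least 100 UMIs and the same direction in at least 75% of matched injury regions. Ppm1d, sex-linked, haemoglobin and region-defining genes and repeated symbols were left out of this ranking. In each list up to 4 members with at least 50 UMIs and the largest absolute log2 ratio could be named. Ccl3, the other Ccl genes and Eif3j1, and the genes given as markers of injury regions within the sections, were chosen after their values were seen. Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, which matched 25200 of the 31053 symbols. No genome sequence was used.

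The alternatives tried were TMM and median-of-ratios scaling, totals without mitochondrial and haemoglobin genes, CPM averaged over spots, CPM standardised over matched regions, other minimum counts for spots, genes and list members, other clusterings, other definitions of injury regions and narrower rings. After the data were seen, injury regions were also compared without region 20, in spots matched on UMIs and with CPM standardised over matched injury regions, other regions without region 15, which met the injury fold in 1 section alone, and lists without members near Ppm1d. The rules were tested on simulated data, made of Poisson draws at the pooled level of each gene with some genes set apart. In whole sections the size rule recovered 46% of genes set 1.5-fold apart and 100% of those set 2-fold apart, and called 24 of 13898 unchanged genes. With 1 in 8 of the spots these were 44%, 98% and 34 of 10118, and lists of unchanged genes stood apart in 4% and 6.5% of draws. The draws held no variation between animals or sections, and not the unequal totals of the injury regions. They therefore cannot say how many genes would be called falsely between 2 animals. Work was done in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and in R 4.3.3 with edgeR 4.0.16. Image files were not analysed here.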

Results

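The data are 2 Visium sections of the ischemic brain hemisphere, 1 from a mouse labelled Ppm1d-/- and 1 from a wild-type mouse. Visium counts the RNA molecules of a tissue section on a grid of barcoded spots, each of which can hold several cells. Both animals were sampled 24 h after a 30 min occlusion of the middle cerebral artery, and the sections were cut at 10 µm. Ppm1d encodes Wip1, a phosphatase that acts on p53 and on other proteins of the DNA damage response. The design asks how Ppm1d affects what follows brain ischemia, with attention to the tissue around the lesion. The section labelled Ppm1d-/- held 53171429 UMIs (molecules counted once) over 2842 spots, with a median of 18629 UMIs and 5277 genes per kept spot. The wild-type section held 53912100 UMIs over 2846 spots, with medians of 18326 UMIs and 5110 genes. There were no replicates, so each difference compares 2 sections without a test, and the 95% intervals cover counting error only.

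Ppm1d itself (chromosome 11, 85311254 to 85347071 in mm10) was not lower in the section labelled Ppm1d-/-. That section held 724 Ppm1d UMIs (95% interval 672 to 779), or 13.6 CPM, and the wild-type section held 670 (620 to 723), or 12.4 CPM. The ratio was 1.10 (0.985 to 1.22), and it was 1.71 (1.32 to 2.22) in injury regions, from 122 against 121 UMIs, and 1.01 (0.902 to 1.14) elsewhere. Visium reads lie near the 3′ end of a transcript, and the position of the deleted part is not given in the sources used here, so the counts give no check of the genotype label. Every direction given here is therefore that of the section labelled Ppm1d-/- over the wild-type section. Both sections carried Y-linked RNA, with 1976 and 1799 Ddx3y UMIs in the section labelled Ppm1d-/- and the wild-type section, against 0 and 1 Xist UMIs.

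Clustering of the spots gave 20 regions, 16 of which held at least 50 spots in each section. Regions 7, 8, 9, 10, 19 and 20 met the rule for injury regions, which rests on 10 genes of the injury response such as Atf3, Hmox1 and Timp1. Region 7 was led by S100a4, Apod, Il33 and Trf, and region 8 by Spp1, Lgals3, Cd14 and Ccl9. Region 9 was led by Acan, Atf3, Hspa1b and Nptx2, and region 10 by Prkcd, Lcn2, Ccl7 and Shox2. Region 19, with 27 and 23 spots, was led by Gng8, Gm5741, Gpr151 and Pou4f1. Region 20, led by the hypothalamic peptide genes Oxt, Avp and Trh, held 96 wild-type spots and 0 of 2841 spots of the other section, and lay apart from the other injury regions. Its counterpart in the section labelled Ppm1d-/- was region 18, also led by Oxt and Trh, with 104 spots there and 12 in the wild-type section.

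**Figure D1:**
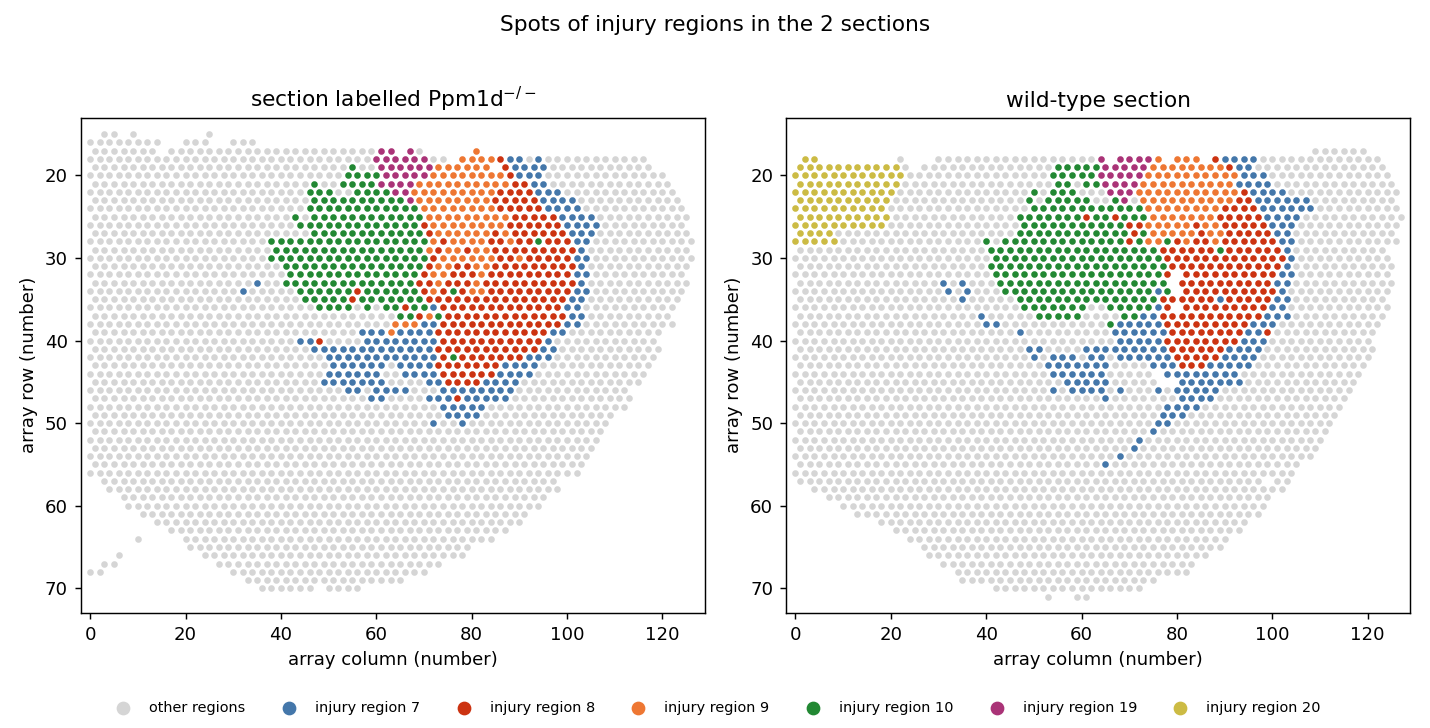
Position of each kept spot by array column and row in the section labelled Ppm1d-/- (left) and the wild-type section (right), with injury regions in colour and other regions in grey. Regions 7 to 10 and 19 form 1 patch in each section, and region 20 lies at the edge of the wild-type section alone.

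Injury regions took a like share of both sections but held fewer RNA molecules per spot in the section labelled Ppm1d-/-. They covered 770 of 2841 spots there, 27.1% (exact binomial interval 25.5 to 28.8), and 815 of 2845 wild-type spots, 28.6% (27.0 to 30.3). Median UMIs per injury spot were 6298 against 11435, while spots of other regions held 22257 against 20625. The gap was widest in region 10, with 4066 against 12384 UMIs per spot, followed by region 9 with 8866 against 14872 and region 8 with 4616 against 6813, while region 19 ran the other way, with 17270 against 14031. Injury regions gave 11.6% of all UMIs in the section labelled Ppm1d-/- and 19.4% in the wild-type section. The share of spots also depends on the section plane and on where the lesion fell, and the genes that define the regions were themselves uneven, Atf3 by 1.97 on the log2 scale in injury regions.

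**Figure D2:**
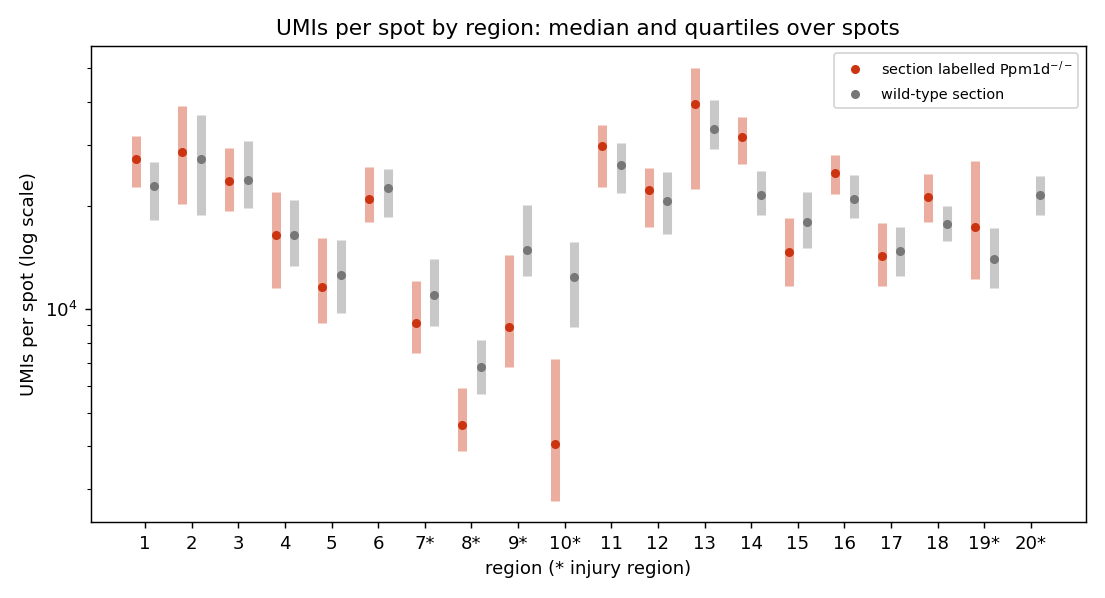
Median UMIs per spot (log axis) with quartiles over spots for each region, in the section labelled Ppm1d-/- (red) and the wild-type section (grey), with injury regions starred. The largest gap as a ratio is in region 10, at 4066 against 12384 UMIs per spot.

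The first comparison asks what marked the injury regions within each section. Log2 ratios of injury over other regions correlated across 12849 genes between the sections (Spearman rho 0.825, across genes, which are not independent replicates). Galectin Lgals3 was higher in injury regions by 3.80 on the log2 scale in the section labelled Ppm1d-/- and by 3.88 in the wild-type section, and the chemokine Ccl2 by 3.48 and 4.28. The osteopontin gene Spp1 reached 814 CPM in injury regions of the section labelled Ppm1d-/- and 315 CPM in those of the wild-type section, against 69.1 and 39.8 CPM elsewhere. Genes of striatal neurons were lower in injury regions, among them Adora2a at -2.84 and -2.50 and Penk at -2.37 and -2.19. Both genes lead region 6, which was not an injury region, while thalamic markers were higher in injury regions, with medians of 0.95 and 1.65. These values can therefore reflect which brain areas the injury regions covered.

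Among the fixed lists, cytokines, chemokines and NF-kB feedback genes had a median log2 ratio of injury over other regions of 3.06 in the section labelled Ppm1d-/- and 2.58 in the wild-type section. All 15 measured members had a positive log2 ratio in the former, and 14 in the latter. Reactive astrocyte genes had medians of 2.48 and 2.85, type I interferon response genes of 1.59 and 2.06, and phagocytic microglia markers of 1.08 and 0.99. The 3 measured neutrophil markers had medians of 3.55 and 2.17, and the 5 monocyte and macrophage markers of 1.94 and 1.77. p53 target genes had a median of 1.04 in the section labelled Ppm1d-/- and 0.53 in the wild-type section, with 14 of 20 members positive in each. Pan-neuronal genes were lower in injury regions of both sections, with medians of -1.21 and -0.64, and none of the 14 was higher. Immediate early genes had medians of 1.54 and 0.60.

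Over whole sections, 209 genes were at least 1.5-fold higher in the section labelled Ppm1d-/- and 109 at least 1.5-fold lower, among 14111 genes with at least 100 UMIs and counting only ratios whose interval excluded 1. Of these genes 14110 had UMIs in both sections, and only such genes were ranked by ratio. The highest ratio in the ranking was that of Eif3j2, a copy of the translation initiation factor gene Eif3j1. It had 842 UMIs against 2, a ratio of 427 and a log2 ratio of 8.74 (6.88 to 11.79). It was higher in 16 of 16 regions, and its counts are uncertain because reads can be split between the near-identical copies. Eif3j1 itself stood at 1717 against 2458 UMIs, a log2 ratio of -0.50. Pla2g4e, which encodes a phospholipase, was 3.23-fold higher (938 against 294 UMIs, log2 1.69) and Tmem87a 2.57-fold higher (924 against 364, log2 1.36, 1.19 to 1.54). These were higher in 11 of 11 and 16 of 16 regions, and they lie on chromosome 2, at 120166412 to 120245630 and 120355309 to 120404154, near Jmjd7, which was lower (log2 -0.88, 110 against 205 UMIs).

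Acan, Mmp3, Thbs1 and Il11 were also among the 12 highest. Acan, the core protein of perineuronal nets, was 3.52-fold higher (924 against 266 UMIs, log2 1.82, 1.62 to 2.02) in whole sections and 2.11 on the log2 scale when standardised over matched regions. The matrix protease gene Mmp3 was 2.94-fold higher (345 against 119 UMIs, log2 1.56), the thrombospondin gene Thbs1 2.86-fold (234 against 83, log2 1.52) and the cytokine gene Il11 2.26-fold (408 against 183, log2 1.18). The interferon-induced GTPase gene Iigp1 was 2.16-fold higher (177 against 83 UMIs, log2 1.11). The remaining high genes were Gm15446 (2.25-fold), Gm4737 (2.16-fold), 9630013A20Rik (2.07-fold) and Oacyl (2.04-fold).

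The lowest genes in the section labelled Ppm1d-/- included the chemokine genes Ccl12 and Ccl4, although the fixed list of cytokines, chemokines and NF-kB feedback had a median of -0.03 (percentile 3.14) with 5 members higher and 7 lower, and one of 0.18 (percentile 98.1) when standardised over matched regions and 0.06 without members within 10 Mb of Ppm1d. The monocyte chemoattractant gene Ccl12 had 461 UMIs against 1474, a log2 ratio of -1.66 (-1.81 to -1.51), and was lower in 13 of 14 regions. Ccl4 had 348 against 724 UMIs, with a log2 ratio of -1.04 (-1.23 to -0.85), and was lower in 7 of 9 regions. Within injury regions Ccl4 stood at -0.76 and elsewhere at -0.11. Of the microglial receptor genes, Gpr34 stood at -1.16 (125 against 283 UMIs) and Cx3cr1 at -0.85 (547 against 1001 UMIs), the latter lower in 16 of 16 regions. The oligodendrocyte enzyme gene Aspa was at -0.95 (439 against 861 UMIs, lower in 15 of 15 regions). It lies on the chromosome of Ppm1d, chromosome 11, at 73304987 to 73326876, outside the 10 Mb examined below. The neuropeptide gene Cort was at -0.93 (521 against 1006). The vasopressin gene Avp was at -1.58 (1175 against 3555 UMIs) and at -2.73 when standardised over matched regions. The other low genes were Gm16867 (-1.31), Tnfrsf25 (-1.07), Myoc (-1.04) and Mns1 (-0.89).

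**Figure D3:**
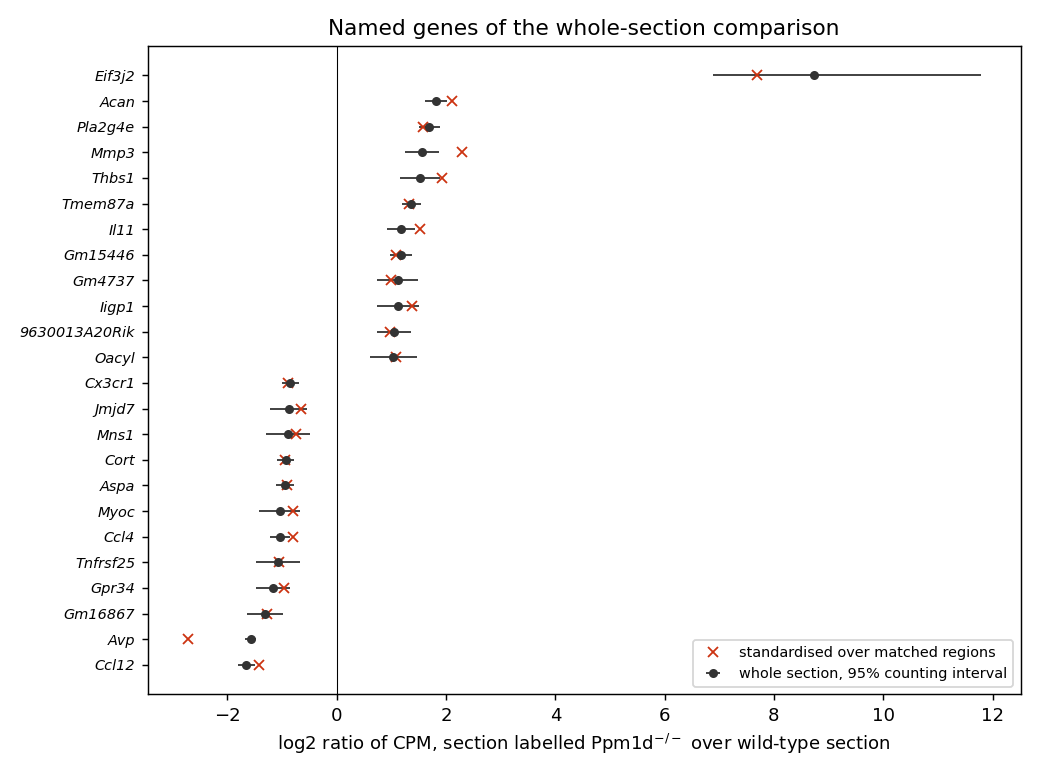
Log2 ratio of CPM, section labelled Ppm1d-/- over wild-type section, for the 24 genes of the whole-section comparison, with 95% counting intervals (black) and the ratio standardised over matched regions (red crosses). Eif3j2 stands at 8.74, with the other 23 genes between -1.66 and 1.82.

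The split of genes by size depended on the scaling. With TMM factors, 138 genes were higher and 179 lower, with median-of-ratios factors 140 and 166, and without mitochondrial and haemoglobin genes in the total 158 and 154, since the median log2 ratio of all genes was 0.08. Standardised over matched regions, 280 genes were higher and 111 lower.

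In fixed lists, homeostatic microglia markers stood apart over whole sections, with a median log2 ratio of -0.29 (percentile 0.00 among random lists of like size and expression). Of 12 members, 6 were lower by at least 0.32 on the log2 scale with an interval excluding 0, and 0 higher, with Sall1 at -0.57 and P2ry12 at -0.52 beside Gpr34 and Cx3cr1. Astrocyte identity genes were low as a group (-0.18, percentile 0.00), with the water channel gene Aqp4 at -0.40 (-0.47 to -0.32). The mitochondrially encoded genes had a median of -0.25 (percentile 0.00), and mitochondrial RNA made up 15.8% of UMIs in the section labelled Ppm1d-/- against 18.7% in the wild-type section. Pan-neuronal genes had a median of 0.16 (percentile 99.94), which was 0.04 and no longer apart when standardised over matched regions. Medians of phagocytic microglia markers (-0.08), reactive astrocyte genes (-0.10) and endothelial and blood-brain barrier genes (-0.07) also lay low, but turned to 0.02, 0.09 and 0.08 when standardised over matched regions. Neutrophil markers (0.26, percentile 89.0) and monocyte and macrophage markers (0.25, percentile 93.2) did not stand apart, but did when standardised (0.57 and 0.66). Whole sections also differed in markers of brain areas, with thalamic markers at -0.32 (percentile 0.00), choroid plexus markers at 0.38 (percentile 100), neocortical markers at 0.20 and striatal markers at 0.19, and red blood cell genes stood at 0.29. Standardised over matched regions these were -0.098, 0.14, 0.09, 0.17 and 0.68, the choroid plexus and neocortical values no longer apart.

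Within injury regions, 629 of 10958 genes were at least 1.5-fold higher in the section labelled Ppm1d-/- and 505 lower. With TMM or median-of-ratios factors 531 were higher and 591 lower. The highest genes included Acan, Npas4, Thbs1 and Fga. Acan, a leading gene of region 9, was 8.34-fold higher (772 against 157 UMIs, log2 3.06, 2.81 to 3.32). The activity-dependent transcription factor gene Npas4 was 7.66-fold higher (289 against 64 UMIs, log2 2.94), Thbs1 6.37-fold (184 against 49, log2 2.67) and the fibrinogen gene Fga 5.16-fold (143 against 47, log2 2.37). Eif3j2 had 191 UMIs against 1 (log2 8.34, 5.84 to 13.65), and Gm5741, Gm42047 and Gm26909 were 10.0-fold, 6.94-fold and 5.62-fold higher, each with enough UMIs in 1 matched injury region alone. With CPM averaged over spots Gm5741 had a log2 ratio of 2.40, against 3.32 from sums.

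The lowest genes of injury regions were peptide genes, of which Oxt, Avp and Trh lead region 20, which the wild-type section alone held. Avp had 6 UMIs against 1976 (log2 -7.60), Oxt 76 against 12644 (-6.62), Trh 20 against 617 (-4.19), Gal 15 against 128 (-2.33) and Crh 29 against 179 (-1.86). Camk1g (-1.73), Igsf1 (-1.66) and Phox2a (-1.65) completed the set. With CPM averaged over spots Oxt stood at -4.98 and Igsf1 at -0.99. Hypothalamic and amygdalar markers had a median of -1.97 (percentile 0.00, over 6 members with UMIs in both sections) with region 20 and 0.21 without it. Without region 20, 480 genes were higher and 364 lower, and standardised over the 4 matched injury regions 365 and 406.

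p53 target genes were higher in injury regions of the section labelled Ppm1d-/-. Their median log2 ratio was 0.54 (percentile 100), with 13 of 22 members higher by at least 0.32 and 0 lower. The cell cycle inhibitor gene Cdkn1a stood at 309 against 162 CPM (log2 0.93, 0.83 to 1.03), Btg2 at 60.7 against 20.1 CPM (log2 1.59, 1.35 to 1.85), the pro-apoptotic gene Bbc3 at 0.89 and Gdf15 at 0.82. The list stood apart in region 9 (0.65, percentile 99.95) and region 8 (0.19, percentile 97.7) but not in region 7 (0.01) or region 10 (0.02). The pooled median was 0.42 without region 20, 0.34 in spots matched on UMIs and 0.25 when standardised over matched injury regions. In other regions it was 0.09 (percentile 54.6), although Cdkn1a was higher there too, at 0.43 (0.35 to 0.51), as was Perp at 0.56 (0.30 to 0.83). The difference between injury and other regions was not tested.

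Inflammatory lists differed unevenly in injury regions. Cytokines, chemokines and NF-kB feedback genes had a median of 0.56 (percentile 100), with 9 of 17 members higher and 3 lower. The cyclooxygenase gene Ptgs2 (log2 2.08, 1.85 to 2.32), Cd14 (1.37, 1.20 to 1.53) and Cxcl1 (1.01, 0.59 to 1.43) were higher, and Ccl12 was lower (-1.54, -1.79 to -1.30). By region the median was -0.66 in region 7 and -0.39 in region 8, both low (percentiles 0.00 and 0.24), 0.21 in region 9 and 0.70 in region 10 (percentile 100). In injury spots matched on UMIs it was -0.03, and over members with at least 100 UMIs 0.18, apart in neither. Without members within 10 Mb of Ppm1d it was 0.84. Neutrophil markers had a median of 0.72 (percentile 99.73), with S100a8 at 1.29 (0.92 to 1.67) and 3 of 6 members higher. Their median was 0.13 in matched spots and 0.53 with injury spots called from summed CPM, apart in neither. By region it ran from -1.19 in region 8 to 1.28 in region 10. Monocyte and macrophage markers had a median of 0.72 (percentile 99.96), with 5 of 8 members higher, among them Pf4 at 1.60 (1.21 to 2.00) and F13a1 at 1.30 (0.58 to 2.03). Haemoglobin genes, as markers of blood in the tissue, were higher alongside, with a median of 0.77 for red blood cell genes and 5 of 5 members higher.

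Homeostatic microglia markers were lower in injury regions, with a median of -0.32 (percentile 0.47), 5 of 12 members lower and 0 higher, and the list no longer stood apart at an injury fold of at least 3 (-0.21). Cx3cr1 stood at -1.16 (-1.54 to -0.80), P2ry13 at -1.08 and Tmem119 at -0.55. Phagocytic microglia markers had a median of 0.13 (percentile 95.6), with Spp1 at 1.37 (1.31 to 1.43), Gpnmb at 0.93 and Lgals3 at 0.90, against Apoe at -0.26. The median was -0.061 in spots matched on UMIs. It stood apart high with averaged CPM (0.11), no UMI minimum (0.16), at least 2000 UMIs per spot (0.17) or members of at least 100 UMIs (0.14). Reactive astrocyte genes had a median of 0.12 (percentile 90.7), with 4 members higher, such as Tm4sf1 at 0.66, and 3 lower, such as S1pr3 at -0.87. Endothelial and blood-brain barrier genes had a median of 0.14 (percentile 89.9), with Cdh5 at 0.59 and Slco1a4 at -0.69, and one of -0.074 in matched spots. They stood apart high with CPM averaged over spots (0.31), at least 2000 UMIs per spot (0.21) and CPM standardised over matched injury regions (0.22).

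Stress and activity programmes were higher in injury regions of the section labelled Ppm1d-/-, while neuronal genes were lower. Immediate early genes had a median of 0.88 (percentile 100), with 9 of 12 members higher, among them Fosl2 at 1.73, Arc at 1.52 and Fos at 1.29. Heat shock genes had a median of 0.35 (percentile 100), with the chaperone gene Hsp90aa1 at 0.56 and Hspa1a at 0.64, and one of 0.18 when standardised over matched injury regions. Genes of the unfolded protein and integrated stress response had a median of 0.27 (percentile 99.79), led by Sesn2 at 1.07 and Chac1 at 1.06, and NRF2 and metallothionein genes one of 0.30 (percentile 99.87), with Slc7a11 at 0.91, the latter at 0.18 and not apart in matched spots. Pan-neuronal genes had a median of -0.39 (percentile 0.00), with 8 of 14 members lower, such as the synaptic vesicle gene Syp at -0.76 (-0.85 to -0.67). Their median was -0.26 when standardised over matched injury regions and -0.15 in matched spots, where it stood apart in 15 of 20 draws. Glutamatergic synapse genes had a median of -0.50 (percentile 0.00), with 9 of 13 members lower, such as Camk2a at -0.80, and the scaffold gene Homer1 higher at 1.04. Thalamic markers were lower in 8 of 9 members (median -0.59), with Prkcd, a leading gene of region 10, at -0.90, but had a median of -0.086 in matched spots and -0.097 at clustering resolution 0.5, apart in neither. Striatal markers had a median of -0.30 (percentile 1.29), and were not apart under 3 alternatives, with values from -0.24 to -0.25. GABAergic neuron genes had a median of 0.07 (percentile 79.6), with Npy at 0.80 and Slc32a1 at -0.68, but stood apart high at 0.32 in matched spots, 0.25 when standardised over matched injury regions and 0.20 without region 20.

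**Figure D4:**
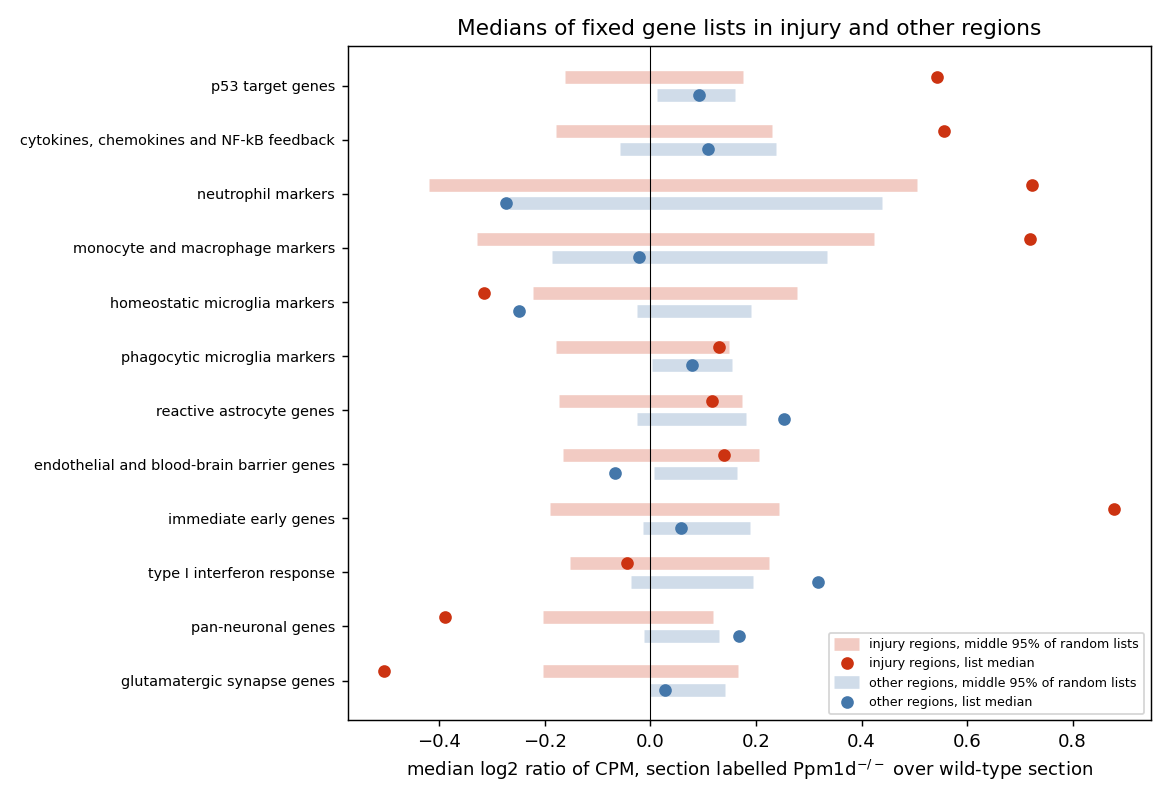
Median log2 ratio of CPM, section labelled Ppm1d-/- over wild-type section, for 12 fixed gene lists in injury regions (red) and other regions (blue), with bars for the middle 95% of 10000 random lists of like size and expression. In injury regions p53 target genes lie at 0.54 and glutamatergic synapse genes at -0.50, and homeostatic microglia markers lie below 0 in both kinds of region.

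Outside injury regions, 214 of 13756 genes were at least 1.5-fold higher in the section labelled Ppm1d-/- and 90 lower. With TMM or median-of-ratios factors these were 138 and 149, and without mitochondrial and haemoglobin genes in the total 157 and 132. Reactive astrocyte genes had a median of 0.25 (percentile 99.95), with 5 of 16 members higher and 0 lower. The lipocalin gene Lcn2 had 3573 against 1230 UMIs (log2 1.43, 1.33 to 1.52), Ptx3 68 against 20 (1.65, 0.92 to 2.45) and Serpina3n 8458 against 4934 (0.66, 0.61 to 0.72). This list stayed above 0 but no longer stood apart with injury spots called from summed CPM (0.08), an injury fold of at least 3 (0.08), no UMI minimum (0.16) or at least 2000 UMIs per spot (0.18). Type I interferon response genes had a median of 0.32 (percentile 99.99), with 6 of 22 members higher and 0 lower, among them Cxcl10 at 1.61 (1.13 to 2.11) and Gbp2 at 0.94. The highest interferon median by region was 0.87 in region 15, led by Six3 and Pvalb, where the injury genes were 2.48-fold up in the section labelled Ppm1d-/- and 1.09-fold in the wild-type section, so that it did not count as injured. Without region 15 the interferon median was 0.24 (percentile 99.1), and it did not stand apart at an injury fold of at least 3 (0.10) or with injury spots called from summed CPM (0.01). Matrix proteases and plasmin system genes had a median of 0.35 (percentile 99.84), with Mmp3 at 1.20, but one of 0.02 over members with at least 100 UMIs.

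Homeostatic microglia markers were lower outside injury regions as well, with a median of -0.25 (percentile 0.00), 5 of 12 members lower and Gpr34 at -1.23 (-1.59 to -0.88). Over the 16 matched regions their median lay below 0 in 16, from -0.79 to -0.06, and at or below percentile 2.5 in 11. Astrocyte identity genes had a median of -0.19 (percentile 0.00) and lay below 0 in 14 regions. The mitochondrially encoded genes had a median of -0.28 (percentile 0.00) and endothelial and blood-brain barrier genes one of -0.07 (percentile 0.05), with Cldn5 at -0.27 (-0.37 to -0.18). Neutrophil markers had a median of -0.27 (percentile 2.27), with S100a9 at -0.88 and Il1r2 at 95 against 31 UMIs, and no longer stood apart under 7 alternatives, among them CPM averaged over spots (-0.09). Medians of cytokines, chemokines and NF-kB feedback (0.11), monocyte and macrophage markers (-0.02) and phagocytic microglia markers (0.08) did not stand apart, but cytokines stood at -0.18 and low with an injury fold of at least 3 (percentile 0.05). The monocyte median was above 0 under 4 alternatives, and the phagocytic was -0.0014 (percentile 2.39) with injury spots called from summed CPM. In the cytokine list Cd14 (0.97), Socs3 (0.79) and Ccl7 (1.15) were higher and Ccl12 lower (-1.23).

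Around the lesion, the spots 1 to 3 array steps from an injury spot numbered 400 in the section labelled Ppm1d-/- and 539 in the wild-type section, and those 4 to 6 steps away 325 and 410. In the nearer ring, reactive astrocyte genes had a median of 0.60 (percentile 100) and cytokines, chemokines and NF-kB feedback one of 0.36 (percentile 99.86). In the outer ring these were 0.16 (percentile 84.6) and 0.09 (percentile 55.6), and farther away 0.46 (percentile 100) and -0.09 (percentile 3.06). Homeostatic microglia markers were lower in both rings, at -0.42 and -0.32 (percentile 0.00 in each), and farther away, at -0.27. Against the farther tissue of the same section, reactive astrocyte genes were higher in the nearer ring by 1.87 in the section labelled Ppm1d-/- and by 1.83 in the wild-type section, and cytokines by 1.42 and 1.18. p53 target genes had medians of 0.03 and 0.05 in the rings. Neutrophil markers, with 4 measured in each ring, had medians of 0.58 and 0.43 (percentiles 92.9 and 86.2). Farther away their median was -0.64 (percentile 0.00) over 6 measured members, so these medians rest on unlike sets of genes. In the rings, monocyte and macrophage markers had medians of 0.43 and 0.28 (percentiles 96.9 and 85.4) and phagocytic microglia markers of -0.06 and 0.07. Those of endothelial and blood-brain barrier genes were 0.01 and -0.10 (percentile 0.48). In a ring of 1 to 2 steps the monocyte median was 0.10 (percentile 57.6). Rings around region 20 exist in the wild-type section alone. Region 15 counted as outside injury, though its injury genes were 2.48-fold up in the section labelled Ppm1d-/- and 1.09-fold in the wild-type section. Its spots can fall in the rings, and rings without it were not tried.

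DNA around a targeted gene can come from another strain, so genes near Ppm1d were examined as a set. The 202 measured genes within 10 Mb of Ppm1d had a median absolute log2 ratio of 0.14, against 0.13 over all genes (percentile 97.0). Of these 202 genes, 8 differed by at least 1.5-fold, against 293 of 13602 genes (2.15%) with a known position. The 8 were the chemokine genes Ccl12, Ccl3 and Ccl4 and also Serpinf2, Dbil5, Efcab5, Wfikkn2 and Abcc3.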

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

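The tests of injury regions without region 20, with CPM standardised over matched injury regions, in spots matched on UMIs and of the share of neurons were chosen only after the list medians had been seen. Values are median log2 ratios, section labelled Ppm1d-/- over wild-type section unless stated.

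Several lists stood apart in opposite directions in injury regions and in other regions, and the difference between the 2 kinds of region was not tested. Neutrophil markers had medians of 0.72 in injury regions and -0.27 in other regions, but 0.13, not apart, in injury spots matched on UMIs, and in other regions the list no longer stood apart under 7 alternatives. Meningeal and fibroblast matrix genes had medians of 0.59 and -0.13, but lay above 0 in 14 of 16 matched regions, and the other-region median was -0.011 over members with at least 100 UMIs and -0.045 with CPM averaged over spots, apart in neither. Myelin and oligodendrocyte genes had medians of 0.17 and -0.070, but lay below 0 in each of the 4 matched injury regions, from -0.35 to -0.05, and the pooled injury median was -0.070 without region 20. Ribosomal protein genes had medians of 0.13 and -0.058, the former 0.079 and not apart in matched spots. Pan-neuronal genes were lower in injury regions, at -0.39, and higher in other regions, at 0.17. Hypothalamic and amygdalar markers stood at -1.97 and 0.40, but region 20, an injury region with 0 and 96 spots, and region 18, outside injury with 104 and 12, share the leading genes Oxt, Avp and Trh. Over matched regions, which leave out both, the median of this list lay below 0 in 11 of 14.

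Other lists had medians of opposite sign for injury over other regions in the section labelled Ppm1d-/- and in the wild-type section, also without a test of the difference. These were the mitochondrially encoded genes, at 0.069 and -0.14, DNA damage signalling genes, at 0.095 and -0.074, and hypothalamic and amygdalar markers, at -1.17 and 1.73, again with region 20 among the injury regions of the wild-type section alone.

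The list medians of injury regions were weighed as 1 pattern, that of p53 target genes, cytokines, neutrophil markers and monocyte and macrophage markers all lying high in the section labelled Ppm1d-/-, at 0.54, 0.56, 0.72 and 0.72. Region 20, held by the wild-type section alone, was not the whole cause, since without it the medians were 0.42, 0.31, 0.63 and 0.58, nor were uneven shares of the injury regions, since standardised medians were 0.25, 0.36, 0.50 and 0.70, all still apart from random lists. A lower share of neurons alone would raise markers of every other cell type alike, but 2 of 4 such lists were low. These were homeostatic microglia markers at -0.32 and oligodendrocyte precursor genes at -0.30, and both lay below 0 in each alternative. Neither was apart with an injury fold of at least 3 (-0.21 and -0.27), nor the former with averaged CPM (-0.29). The latter was not apart at resolution 0.5 or with summed CPM (-0.16 in both). Markers can also change within their cells, and pan-neuronal genes were low (-0.39), so fewer neurons may still play a part. Fewer UMIs per spot may account for the cytokine and neutrophil medians. These were -0.025 and 0.13 in 402 spots per section matched on UMIs and stood apart high in 0 of 20 draws. The p53 median (0.34) did so in 20 and the monocyte and macrophage median (0.45) in 18, which leaves depth open for the last. Matching took equal numbers of spots per region from the 2 sections, but did not keep each region's share as in all injury spots. Region 10, where cytokines and neutrophil markers lay high, had 4066 against 12384 UMIs per spot. For these lists an effect of depth and a changed weight of the regions in the matched spots therefore cannot be told apart. A low UMI count could itself follow from injury, and genotype, animal and section cannot be told apart with 1 section of each, so an effect of Ppm1d stays open and untested.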

How the results depend on the processing

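The alternatives without region 20, with spots matched on UMIs and with CPM standardised over matched injury regions, the one without region 15, and lists without members near Ppm1d, were chosen after the data were seen. No paired analysis was possible because each genotype had 1 section. Values are median log2 ratios of lists unless stated, and the cause was not tested for values that moved. Of the alternative values of the main results, 333 kept their call and 14 moved, 15 came to stand apart, 16 ceased to and 11, apart under either setting, changed sign; for the other lists and named genes the counts were 1326, 18, 35, 55 and 25. A further 11 and 72 changed sign without being apart in either setting, and are counted among those that kept their call. So are 88 and 341 calls of lists that could not change, under scaling that moves all genes alike and an injury fold of 1.5, which gave the same regions. In the 12 other alternatives, p53 target genes in injury regions stood apart in each (0.25 to 0.62), as did monocyte and macrophage markers (0.45 to 0.83). TMM factors moved whole-section log2 ratios by -0.085. Ppm1d stood between 0.05 and 0.26. Of the named genes, 18 values moved, all with CPM averaged over spots or standardised over matched regions. Averaging gave 2.40 for Gm5741, -4.98 for Oxt, -3.34 for Trh and -0.99 for Igsf1 in injury regions, and 1.82 for Il11 and 2.18 for Mmp3 in whole sections, where standardising gave -2.73 for Avp.

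Standardised over matched regions, whole-section medians were 0.18 for cytokines, 0.57 for neutrophil markers, 0.66 for monocyte and macrophage and 0.019 for phagocytic microglia markers, 0.090 for reactive astrocyte, 0.084 for endothelial, 0.091 for meningeal, 0.014 for ribosomal protein, 0.026 for type I interferon response and -0.078 for glutamatergic synapse genes. Before standardising these were, in the same order, -0.032, 0.26, 0.25, -0.082, -0.10, -0.072, -0.13, -0.078, -0.060 and 0.049. With CPM averaged over spots they were 0.23, 0.87, 0.56, 0.064, 0.090, 0.12, 0.11, 0.027, 0.045 and -0.072, and p53 target genes stood at 0.15. That averaging also gave, in injury regions, 0.31 for endothelial genes, -0.29 for homeostatic and 0.11 for phagocytic microglia markers and -0.060 for myelin genes, and, in other regions, -0.092 for neutrophil markers and -0.018 for glutamatergic synapse genes. It turned the split of injury-region genes to 467 higher and 645 lower.

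With at least 2000 UMIs per spot, cytokines stood at -0.059 in whole sections, endothelial genes at 0.21 and phagocytic microglia markers at 0.17 in injury regions, and neutrophil markers at -0.27 and reactive astrocyte genes at 0.18 in other regions. With no UMI minimum, phagocytic microglia markers stood at 0.16 in injury regions and reactive astrocyte genes at 0.16 in other regions. With members of at least 100 UMIs, cytokines stood at 0.18 in injury regions and -0.071 in whole sections, hypothalamic markers at -0.072 in whole sections, neutrophil markers at -0.26 in other regions and phagocytic microglia markers at 0.14 in injury regions. Fewer genes pass a higher count minimum: with at least 20 UMIs 622 whole-section and 592 other-region genes were apart by size, and with at least 500 these were 75 and 69, with 389 in injury regions.

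At clustering resolution 0.5, injury regions took 31.1% of the spots labelled Ppm1d-/- and 32.7% of wild-type spots, and 677 genes were apart by size there. With genes scaled over both sections together, neutrophil markers stood at -0.25 in other regions. With an injury fold of at least 3, the shares were 19.7% and 17.6%, and medians in injury regions were -0.21 for homeostatic microglia, 0.21 for hypothalamic and -0.28 for myelin genes, and in other regions -0.18 for cytokines, -0.086 for neutrophil markers, 0.082 for reactive astrocyte genes and -0.026 for thalamic markers. With injury spots called from summed CPM, the shares were 22.6% and 21.6%, neutrophil markers stood at 0.53 in injury and -0.15 in other regions, and type I interferon response genes at 0.27 in injury regions. In other regions that call gave -0.0014 for phagocytic microglia markers, 0.078 for reactive astrocyte genes, -0.082 for thalamic markers and -0.0023 for the unfolded protein response.

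In injury spots matched on UMIs, cytokines stood at -0.025, neutrophil markers at 0.13, reactive astrocyte genes at 0.19, choroid plexus markers at -0.060, hypothalamic markers at 0.22 and myelin genes at -0.17, with 603 genes by size. Without region 20, the wild-type share was 26.2%, hypothalamic markers stood at 0.21 and myelin genes at -0.070. Without region 15, neutrophil markers stood at -0.24 in other regions. Standardised over matched injury regions, endothelial genes stood at 0.22, choroid plexus markers at -0.11, hypothalamic markers at 0.19 and myelin genes at -0.082. Without members near Ppm1d, cytokines stood at 0.84 in injury regions and 0.056 in whole sections. In a nearer ring of 1 to 2 steps, medians were 0.55 for reactive astrocyte genes, 0.49 for cytokines, 0.46 for neutrophil and 0.10 for monocyte and macrophage markers. The outer ring of 3 to 4 steps gave 0.13 for reactive astrocyte genes, 0.14 for cytokines and 0.26 for monocyte and macrophage markers, but no value for neutrophil markers, since too few were measured. In simulated whole sections, differences set at 1.5-fold, the cut-off itself, were called in 46% of genes, and 2-fold differences in 100%. A gene not called can therefore still differ by about the cut-off.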

Other observations

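The tests of uneven regions and of fewer microglia, the comparisons without region 15 or region 20, in matched spots and standardised over matched injury regions were chosen only after the values concerned had been seen. Values are log2 ratios of CPM, section labelled Ppm1d-/- over wild-type section, as list medians where a list is named.

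The injury regions differed in which lists stood apart. In region 10, led by Prkcd, Lcn2 and Ccl7, type I interferon response genes (0.37, percentile 99.94), the 3 measured neutrophil markers (1.28), endothelial and blood-brain barrier genes (0.59), phagocytic microglia markers (0.21) and matrix proteases (1.05) were high. Haemoglobin genes were high there as well, with a median of 1.97 for red blood cell genes, and among injury regions this one had the largest gap in UMIs per spot. In region 8, led by Spp1 and Lgals3, interferon response genes (-0.96) and neutrophil markers (-1.19) were low and cell cycle genes, with 4 measured, high (percentile 99.99). In region 9, led by Acan and Atf3, interferon response genes (-0.58), astrocyte identity genes (-0.58), GABAergic neuron genes (-0.72) and glutamatergic synapse genes (-1.24) were low, while NRF2 and metallothionein genes (0.53) and unfolded protein response genes (0.53) were high. Immediate early genes were high in regions 7 to 10, from 0.27 in region 8 to 1.15 in region 9. Meningeal and fibroblast matrix genes were high in the same regions, from 0.29 in region 7 to 1.05 in region 9.

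Vascular lists differed in injury regions, with activated endothelium genes at 0.28 (percentile 97.9) against 0.12 in other regions, the former not apart under 7 alternatives (0.23 to 0.27), and mural cell markers at -0.17 and -0.04. Neither mural value stood apart, but that of injury regions did under 3 alternatives, at -0.31 with genes scaled over both sections together, -0.29 at clustering resolution 1.5 and -0.52 with injury spots called from summed CPM. Matrix proteases stood at 0.27 in injury regions (percentile 97.2), and high and apart under 8 alternatives, from 0.29 to 0.58. Oligodendrocyte precursor genes were low in injury regions (-0.30, percentile 1.14) and in other regions (-0.09, percentile 0.13), the former not apart at clustering resolution 0.5 (-0.16), with summed CPM (-0.16) or with an injury fold of at least 3 (-0.27). Cell cycle genes were high in injury regions, at 0.52 (percentile 99.3), with the cyclin gene Ccnb1 at 68 against 9 UMIs, and stood at 0.21 elsewhere, but in matched injury spots the list was also at 0.21, and it was not apart under 6 alternatives. With an injury fold of at least 3 the value elsewhere was 0.31 and apart (percentile 98.3). DNA damage signalling genes did not stand apart, at -0.16 and 0.11, nor did programmed cell death genes, at 0.06 and -0.03, hypoxia and glycolysis genes, at 0.12 and 0.13, or nuclear-encoded respiratory chain genes, at -0.10 and 0.03. Type I interferon response genes stood at -0.04 in pooled injury regions, but low and apart without region 20 (-0.17, percentile 0.57), standardised over matched injury regions (-0.27, percentile 0.16) with an injury fold of at least 3 (-0.23, percentile 0.99) and in spots matched on UMIs (-0.27, low in 19 of 20 draws). With injury spots called from summed CPM they were high instead (0.27, percentile 99.2). Complement and MHC class I genes stood at -0.00 in injury regions and -0.03 in other regions, the latter low (percentile 1.21) but not apart with CPM averaged over spots (-0.0067) or without region 15 (-0.014). The 3 lymphocyte markers measured in injury regions had a median of 0.57 (percentile 91.5), and 5 measured elsewhere one of -0.02.

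Among markers of brain areas, choroid plexus and ependyma markers were high in pooled injury regions (0.54) and in other regions (0.45, but 0.064 and not apart with injury spots called from summed CPM). The injury value turned to -0.11 when standardised over matched injury regions and to -0.060 in matched spots, and was -0.03 in region 7, 2.58 in region 9 (3 measured) and 0.06 in region 10. Red blood cell genes stood at 0.30 in other regions (percentile 99.9) and at 0.18, not apart, without region 15. Neocortical layer markers stood at 0.03 and 0.13 and hippocampal markers at -0.19 and 0.05 in injury and other regions, none of them apart. Hippocampal markers were low and apart in injury regions with an injury fold of at least 3 (-0.40), in matched spots (-0.57) and standardised over matched injury regions (-0.74), and neocortical markers high in other regions with that fold (0.18). In other regions thalamic markers stood at 0.03 and striatal markers at 0.11, within the random lists, but the thalamic value was low and apart with summed CPM (-0.082) and with an injury fold of at least 3 (-0.026).

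Eif3j2, Pla2g4e, Tmem87a and Jmjd7 were weighed as a pattern, and since the rule that named them asked for 1 direction over regions, uneven regions were not tested for them. For Eif3j2, a candidate explanation is a shift of reads between paralogs, since the scaled loss of UMIs at Eif3j1 equalled 84.2% of the gain at Eif3j2 and the sum of both genes was 2559 against 2460 UMIs (log2 0.08, -0.00 to 0.16). Eif3j2 lies on chromosome 18, but Eif3j1 lies on chromosome 2 at 122028580 to 122053632, near the other 3 genes, so a variant at Eif3j1 could move reads to its copy. A strain variant in that stretch of DNA cannot be told apart from chance by counts alone, since 3 of 87 other genes within 5 Mb differed by size (3.45%, 0.717 to 9.75) against 2.15% of all 13602 genes, a ratio of 1.60. The window of 5 Mb from 115000001 on chromosome 2, next to these genes, held 4 such genes of 43, among them Thbs1. This was the highest number over 425 windows but shared with 3 others. The windows that follow, from 120000001 to 135000000, each held 3 such genes, of 45, 50 and 48. Those of the first were Pla2g4e, Tmem87a and Jmjd7. Those of the last included Oxt and Avp, which lead an injury region held by the wild-type section alone. Whether such a run of windows exceeds chance was not tested, so strain stays open. An effect of genotype on these genes was not tested apart from strain.

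Ccl12 (-1.66), Ccl4 (-1.04) and Ccl3 (-0.63) were low in whole sections and lie on chromosome 11 within a few Mb of Ppm1d, where the annotated spans of Ccl3 and Ccl4 overlap, but Ccl3 stood at -0.27 in injury regions and 0.13 in other regions. Of other chemokine genes, Ccl2 (-0.40), Ccl7 (-0.54), Ccl6 (-0.30), Ccl9 (0.19) and Ccl5 (0.10) stood at 0.19, -0.082, 0.084, 0.65 and 0.72 standardised over matched regions. DNA flanking the targeted gene could differ by strain. Within 5 Mb of Ppm1d 0 of 85 other genes differed by size, a ratio of 0 to the share of all genes, but the interval reaches 4.25%, above 2.15%. Within 10 Mb 8 of 202 did, these 3 genes among them. The windows of 5 Mb from 65000001 to 85000000 on chromosome 11 each held 3 such genes, of 67, 68, 83 and 52. Those of the last window were the 3 Ccl genes, and Aspa lay in the second. Strain therefore stays open. Fewer microglia may play a part, since the highest upper bound of the 3 genes, -0.40 for Ccl3, lies above the lower quartile of homeostatic microglia markers, -0.53, although the upper bounds of Ccl12 and Ccl4, -1.51 and -0.85, lie below it. Uneven regions also stay open, with Ccl3 at -0.30 standardised over matched regions, and with Ccl12 at -1.42 and Ccl4 at -0.80 there, genes that were named by a rule asking for this direction, and an effect of Ppm1d was not tested apart from animal and section.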
